A study of Mus musculus with 6 samples.

How the data were processed

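RNA-seq was carried out on Nes-CFP-positive cells sorted from dissociated cerebella of Nes-CFP/+ Swiss Webster mice at postnatal day 5, with 3 libraries from mice irradiated at postnatal day 1 and 3 from non-irradiated mice. Per the labels' protocols, cerebella were dissociated with papain, RNA was extracted with Trizol, and poly(A)-selected libraries were made from 100 ng of RNA. The submitters' processing notes name HTSeq, DESeq and genome build mm10, with no version or role. The aligner and the strandedness of library and counting are not given in the sources used here.

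The deposited table holds 1 value per gene and library for 19630 genes, a signal scaled by the authors rather than raw counts or coverage. From the values, each is a read count divided by a DESeq size factor of the library, with 1 added by the authors. After the 1 was taken off, every value in every library (100%) was a whole multiple of the value of 1 read, within 0.001 reads, with a largest distance of 4.83e-05. The factors recovered in this way, 0.953 to 1.17, equal the median-of-ratios factors of the recovered reads. The lowest sum of reads over the 6 libraries was 15, held by 152 genes, so genes with fewer reads are not analysed here. A symbol had been turned into a date in 25 rows and was replaced through the gene ID. Of the gene IDs 19542 matched GENCODE release M21 on GRCm38, the assembly that mm10 names, and 88 did not. Coordinates are 1-based and from that annotation, which may not be the one the authors counted on.

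Depth was 30986269 to 37067530 gene-assigned reads per library. For genes with few reads in a group, the ratio of summed reads scaled by the size factors is given with an exact Clopper-Pearson interval at 95%. Such intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Between libraries of 1 group, chi-square per degree of freedom over genes was 17.5 to 58.5, and 16.96 to 67.65 between groups, so no pair looked like a repeat deposit of 1 library. This does not show that the libraries are independent samples, and they were used as replicates because the labels list them as separate samples.

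The main test was limma-trend (limma 3.58.1, R 4.3.3) on log2(scaled count + 1), which is the log2 of the deposited value, in genes with a mean scaled count of at least 10 over the 6 libraries (16674 genes). Genes were called at a Benjamini-Hochberg adjusted p below 0.05, two-sided. A fold change on this scale understates the change of low genes. For gene lists, camera was run with a preset inter-gene correlation of 0.01 and adjusted over the 28 lists, and camera with an estimated correlation and fry were the alternatives. The lists, the tests, the alternatives below and the rule for named genes were fixed before the data were examined. The rule names *Nes*, *Atoh1*, *Gli1* and *Cdkn1a*. It also names up to 8 genes with the largest rise and 8 with the largest fall among those past the threshold with a mean of at least 50 and no overlap of the groups, leaving out predicted, mitochondrial and ribosomal protein genes. In each list it takes up to 4 members past the threshold, or the member with the highest mean where none passed. The other genes named were chosen after their values were seen. They are *Foxa2* and *Cdh1*, members that passed over a list alone, *Mki67*, the 6 genes of the granule progenitor test in the closing section, and the genes outside the lists there. Some genes that the rule or the lists would name are not reported here, and the test on Hedgehog genes in the closing section was run again without such a gene, which changed its outcome from arguing against the explanation to undecided.

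The lists cover granule cell progenitors, granule neuron differentiation, the Hedgehog and Notch pathways, neural stem and radial glial cells, Bergmann glia, astrocytes, GABAergic interneurons, oligodendrocytes, microglia, endothelium, pericytes, fibroblasts, Purkinje cells, ependyma and choroid plexus, erythroid cells, p53 targets, S phase, G2/M phase, interferon response, inflammatory mediators, immediate early and heat shock genes, migration and adhesion, WNT and BMP targets, cholesterol synthesis, glycolysis and hypoxia, mitochondrially encoded genes and sex-linked genes.

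Control and irradiated libraries carry the same replicate numbers in the labels. Deviations from the group means over the 16674 genes correlated by 0.305, 0.151 and 0.451 (across genes, which are not independent) between same-numbered libraries 1, 2 and 3, and by -0.342 to 0.05 between libraries of different number. Each pair exceeded 0.1, so the numbers were taken to pair the samples. The pairing comes from the data, as the labels do not say what a number shares. The evidence is limited, since deviations cancel within a group, so some matching of the numbers tends to correlate positively. The main test, fixed before the data were examined, leaves the pairing out, and the replicate block is given as an alternative.

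Alternatives were pseudocounts of 0.5 and 5, no filter on low values, a mean of at least 50, TMM factors, quantile normalization, edgeR's quasi-likelihood test (edgeR 4.0.16) and DESeq2 (1.42.0) on the recovered reads, the replicate number as a block, and leaving out each library in turn. After seeing the data, 2 were added, namely edgeR with the block and the mean log2 level of *Ddx3y*, *Eif2s3y*, *Kdm5d* and *Uty* as a covariate. DESeq2 left 328 adjusted p-values as NA. The fits were tested on 5 simulated data sets of the 16674 genes for irradiated against control, with 200 genes changed in each. limma called 67.4% of the genes changed 2-fold and 95.8% of those changed 4-fold, and on average 9.8 unchanged genes. The figures for edgeR were 68.0%, 95.4% and 11.2 genes, and for DESeq2 74.6%, 93.6% and 34.2 genes. Of 140 list tests on the simulated data camera called 0. Genes were drawn independently in the simulation, whereas the estimated correlation within the real lists reached 0.917, for microglia and macrophage genes. The simulation therefore does not test the preset correlation. Figures were drawn with matplotlib.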

Results

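Transcriptomes of Nestin-expressing cells were measured in the neonatal mouse cerebellum. Cells carrying a cyan fluorescent reporter of the *Nes* gene (Nes-CFP) were sorted by flow cytometry from Swiss Webster mice at postnatal day 5, either after irradiation at postnatal day 1 or without irradiation. *Nes* encodes Nestin, an intermediate filament protein of neural progenitors and glia. Poly(A)-selected RNA was sequenced from 3 libraries per group, 6 in all. The control libraries held 31130326, 31591682 and 37067530 reads assigned to the 19630 listed genes. The irradiated libraries held 30986269, 31048693 and 31070520. Values below are read counts scaled by the authors' DESeq size factors, given as mean ± SD with n = 3 per group. Log2 fold changes are irradiated minus control on the log2(scaled count + 1) scale with their standard error (SE). The labels do not say whether the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical in part. Sex-linked transcripts, given below, differed between libraries of 1 group, so not all of that spread is technical.

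The first question was which genes differed between sorted cells of irradiated and non-irradiated cerebella. *Cdkn1a*, which encodes the cell cycle inhibitor p21, rose from 308 ± 85.0 to 1715 ± 212 (log2 fold change 2.50, SE 0.20). *Ephx1*, encoding microsomal epoxide hydrolase, rose from 206 ± 39.0 to 752 ± 160. *Phlda3*, a p53-induced inhibitor of Akt, rose from 134 ± 25.5 to 475 ± 92.5. The p53-induced long noncoding RNA *Trp53cor1* rose from 28.3 ± 4.74 to 148 ± 42.0, and *Slc39a12*, encoding a zinc transporter, from 309 ± 29.8 to 655 ± 12.1. *Fam107a* fell from 1052 ± 109 to 491 ± 40.4 (log2 fold change -1.10, SE 0.14). The forkhead gene *Foxa2* and the E-cadherin gene *Cdh1* also passed, with almost no reads in one of the groups. *Foxa2* had 5 reads over the control libraries and 99 over the irradiated ones, a scaled ratio of 21.3 with a 95% Clopper-Pearson counting interval of 8.82 to 67.0. *Cdh1* had 131 reads over the controls and 3 over the irradiated libraries, a control to irradiated ratio of 40.6 with an interval of 13.6 to 199.6.

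These genes were among the 9 of 16674 tested that passed limma-trend at a Benjamini-Hochberg adjusted p below 0.05, 7 higher and 2 lower, and all 9 changed at least 2-fold. In all 9 the irradiated and control libraries did not overlap, as for 8.83% of the genes tested, where chance gives 10% for 3 against 3. The limma adjusted p was 0.00372 for *Cdkn1a*, 0.0205 for *Ephx1*, *Foxa2* and *Cdh1*, 0.0316 for *Phlda3*, 0.035 for *Trp53cor1* and *Fam107a*, and 0.0411 for *Slc39a12*. At an unadjusted limma p below 0.05, 751 of the 16674 genes passed, under the share of 0.05 that chance alone gives. Other splits of the 6 libraries into 3 and 3 gave 125 to 2395 such genes. DESeq2 on the recovered reads called 104 genes, and limma with the replicate number as a block called 25 genes, 21 higher and 4 lower. With the level of Y-linked genes as a covariate, an alternative added after seeing the data, 28 genes were called, 7 of them among the 9. The count was 2, 1 and 3 without control replicate 1, 2 and 3, 29 without irradiated replicate 1 and 3 without irradiated replicate 2. *Cdkn1a* passed in each of 17 alternative settings, at adjusted p from 3e-28 to 0.0487. *Ephx1*, *Phlda3* and *Trp53cor1* each missed the threshold when control replicate 1, 2 or 3 or irradiated replicate 2 was left out, at limma adjusted p from 0.0668 to 0.365. *Cdh1* missed it when control replicate 1, 2 or 3 was left out, at a limma adjusted p of up to 0.167. *Fam107a* and *Foxa2* missed it when a library other than irradiated replicate 1 was left out, at up to 0.33 and 0.149, and *Slc39a12* when any of the 6 was, at up to 0.469. *Cdh1* and *Slc39a12* also missed it with the Y-linked covariate (limma adjusted p = 0.061 and 0.099). *Slc39a12* further missed it among genes with a mean of at least 50 (limma adjusted p = 0.057) and with edgeR (adjusted p = 0.0506). Under edgeR with the block the adjusted p was 0.0514 for *Phlda3*, *Fam107a*, *Foxa2*, *Cdh1* and *Slc39a12*.

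**Figure D1:**
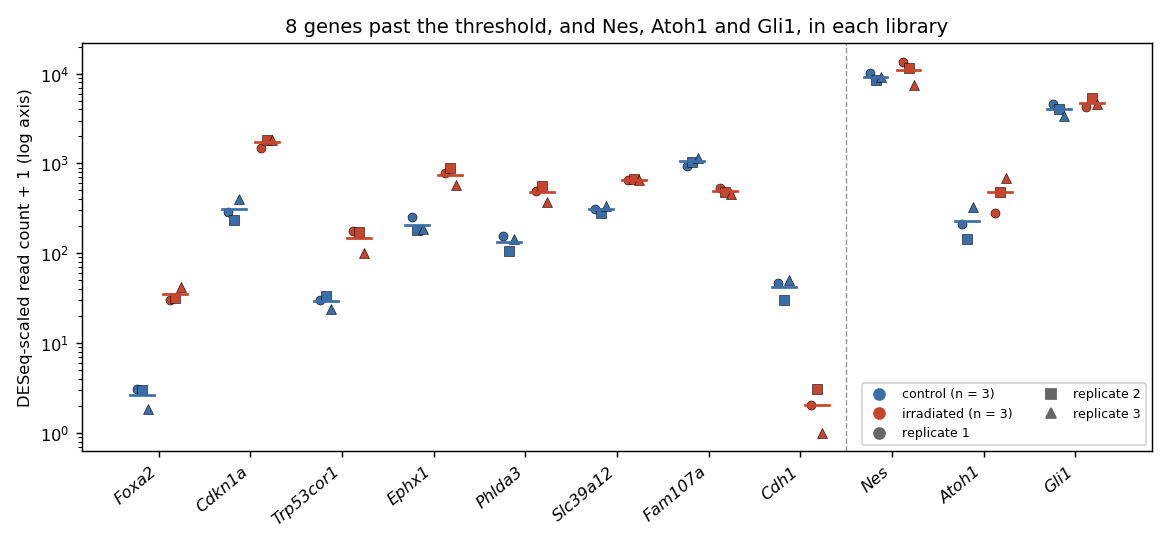
Scaled read count + 1 (log axis) of each library for 8 of the 9 genes past the threshold, to the left of the dashed line, and for *Nes*, *Atoh1* and *Gli1*. Points are libraries, with symbols for the replicate number, and bars are group means (n = 3 control, n = 3 irradiated). The groups do not overlap for any of these 8, with *Cdkn1a* at 308 ± 85.0 in controls and 1715 ± 212 after irradiation, and they overlap for *Nes*, *Atoh1* and *Gli1*.

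In GRCm38 coordinates of the GENCODE annotation, *Cdkn1a* (ENSMUSG00000023067.13) lies on chromosome 17 from 29090976 to 29100727 on the plus strand, and *Trp53cor1* (ENSMUSG00000085912.1) lies near it from 29057430 to 29079179 on the minus strand. *Ephx1* (ENSMUSG00000038776.13) lies on chromosome 1 from 180976210 to 181020904, and *Phlda3* (ENSMUSG00000041801.5) on chromosome 1 from 135766119 to 135769136. *Slc39a12* (ENSMUSG00000036949.16) lies on chromosome 2 from 14388316 to 14494977, *Foxa2* (ENSMUSG00000037025.11) on chromosome 2 from 148042877 to 148046969, *Fam107a* (ENSMUSG00000021750.15) on chromosome 14 from 8296274 to 8318023, and *Cdh1* (ENSMUSG00000000303.12) on chromosome 8 from 106603351 to 106670246. All are protein-coding genes except *Trp53cor1*, a long intergenic noncoding RNA. Of the 9, *Cdkn1a* and *Trp53cor1* overlap annotated genes on the opposite strand and *Ephx1* overlaps one on its own strand. The sources used here do not say whether counting used strand, so reads of such partners cannot be told apart.

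Among 30 measured p53 target genes, 26 had a higher fitted level after irradiation and 4 a lower one. *Cdkn1a* and *Phlda3* passed limma over all genes tested, and 13 rose adjusted over the list alone. Among the 13, *Ccng1*, encoding cyclin G1, rose from 1772 ± 134 to 3302 ± 689, and *Sesn2*, encoding the stress protein sestrin 2, from 503 ± 126 to 1074 ± 291. *Eda2r*, of the tumour necrosis factor receptor family, rose from 981 ± 164 to 1979 ± 294, and *Pmaip1*, encoding the proapoptotic protein Noxa, from 39.2 ± 8.79 to 179 ± 102. *Ccng1* and *Sesn2* passed over all genes with the replicate block (limma adjusted p = 0.0442 and 0.0388) and not without it (limma adjusted p = 0.169 and 0.339). Under edgeR with the block the adjusted p was 0.0514 and 0.0473, and DESeq2 without the block called both (adjusted p = 0.000145 and 0.00322). The list was shifted upward, with a median log2 fold change of 0.38 (camera adjusted p = 7.04e-20 over 28 lists). Its adjusted p was 0.113 with an estimated correlation, the highest over 19 alternatives. The list kept its direction and its camera call without each of the 6 libraries in turn.

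The study's title names granule cells and Nestin-expressing progenitors, so genes of the progenitor lineages were compared next. *Nes* itself stood at 9180 ± 833 in controls and 10836 ± 3079 after irradiation (log2 fold change 0.20, SE 0.20, limma adjusted p = 1). *Atoh1*, the transcription factor of granule cell progenitors, stood at 225 ± 91.1 and 482 ± 199 (log2 fold change 1.08, SE 0.36), and did not pass (limma adjusted p = 0.837, lowest of its 17 alternatives 0.147). Over these alternatives its log2 fold change ran from 0.421, with the Y-linked covariate, to 1.42. Of 18 granule cell progenitor genes, 10 had a higher and 8 a lower fitted level, and none passed over all genes. *Olig3*, a transcription factor gene of hindbrain progenitors, rose adjusted over the list alone, from 6.19 ± 4.17 to 33.8 ± 15.5. With the replicate block 3 rose adjusted over the list alone, namely *Olig3*, *Atoh1* and *Neurod1*. *Zic1*, the member with the highest level, stood at 30054 ± 693 and 29065 ± 1032. The list had a median log2 fold change of 0.0315 and did not pass (camera adjusted p = 0.148; adjusted p = 0.598 with an estimated correlation). It passed without control replicate 3 (median 0.15, camera adjusted p = 0.00941), without irradiated replicate 1 (median 0.17, camera adjusted p = 0.00171) and in edgeR with the block (camera adjusted p = 0.02). Its median turned to -0.0602 with the Y-linked covariate (camera adjusted p = 0.315). The granule neuron differentiation list, 13 of 19 higher and 6 lower with no member past the threshold, had a median of 0.0313 (camera adjusted p = 0.915), and its highest member *Nrep* stood at 26914 ± 1089 and 25461 ± 361. That list passed upward without irradiated replicate 1 (median 0.12, camera adjusted p = 0.0286), and downward with the Y-linked covariate (median -0.22, camera adjusted p = 0.00326).

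Hedgehog signalling drives granule cell progenitor division, and its target *Gli1* stood at 3999 ± 582 in controls and 4747 ± 577 after irradiation (log2 fold change 0.25, SE 0.14, limma adjusted p = 1). Of 18 Hedgehog pathway genes 10 had a higher and 8 a lower fitted level after irradiation. None passed limma over all genes, and 4 rose adjusted over the list alone. Among the 4, the receptor gene *Ptch1* rose from 9765 ± 661 to 13751 ± 2029. The secreted frizzled-related protein gene *Sfrp1* rose from 1284 ± 355 to 3078 ± 1261, and the cyclin gene *Ccnd1* from 7269 ± 1696 to 12829 ± 1305. DESeq2 called *Sfrp1* and *Ccnd1* over all genes (adjusted p = 0.00431 and 0.00155). *Ccnd2*, the highest member, stood at 33502 ± 2342 and 36262 ± 2197. The list median was 0.0415 (camera adjusted p = 0.0101), and the adjusted p was 0.525 with an estimated correlation. The camera call ended without control replicate 2 (adjusted p = 0.0557), without irradiated replicate 2 (adjusted p = 0.271, median -0.00685) and with the Y-linked covariate (adjusted p = 0.146). The Notch pathway list, with *Notch1* at 12510 ± 1532 and 11427 ± 1939, did not pass (median -0.0851, camera adjusted p = 0.15). It passed downward without control replicate 2 or irradiated replicate 2 (camera adjusted p = 0.0476 and 0.0166). Genes of migration and adhesion did not pass either (median -0.10, camera adjusted p = 0.222), with *Nrcam* at 17293 ± 2324 and 16207 ± 2344. They passed downward without the same libraries (camera adjusted p = 0.0322 and 0.0104). For WNT and BMP targets, with *Id2* at 10123 ± 1786 and 9730 ± 145, the camera adjusted p was 0.855, with a median of -0.0425 against a mean of 0.0176 and an upward test.

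In the Bergmann glia list 12 of 15 members had a lower fitted level after irradiation and none passed limma over all genes. *Gpr37l1*, a glial receptor gene, fell adjusted over the list alone from 25637 ± 2427 to 16909 ± 2332, and DESeq2 called it over all genes (adjusted p = 0.00628). The highest member, the glutamate transporter gene *Slc1a3*, stood at 219189 ± 33323 and 199173 ± 49432. With the block 4 Bergmann glia genes fell adjusted over the list alone, *Gpr37l1*, *Timp4*, *Etv4* and *Etv5*. The list was shifted downward (median -0.20, camera adjusted p = 0.000701; adjusted p = 0.556 with an estimated correlation). It did not pass without control replicate 1 (camera adjusted p = 0.353) or irradiated replicate 3 (camera adjusted p = 0.519), and its median was 0.0862 with the Y-linked covariate (camera adjusted p = 0.514). Of 18 astrocyte genes 15 were lower in the fit and none passed, with *Sparcl1* at 173320 ± 19229 and 145202 ± 26192. The astrocyte list was shifted downward (median -0.26, camera adjusted p = 4.48e-05; adjusted p = 0.366 with an estimated correlation). In the GABAergic interneuron lineage 15 of 16 genes were lower in the fit. *Pax2*, which marks interneuron precursors, fell adjusted over the list alone from 605 ± 117 to 296 ± 71.2, as did the glycine transporter gene *Slc6a5*, from 129 ± 68.2 to 43.7 ± 11.0. *Pax2* passed over all genes with the block (limma adjusted p = 0.0442) and not without it (limma adjusted p = 0.237). Its adjusted p was 0.0514 under edgeR with the block, and DESeq2 without the block called *Pax2* and *Slc6a5* (adjusted p = 0.00166 and 0.026). With the block *Pax2*, *Slc6a5*, *Lhx5* and *Tfap2a* fell and *Nrk* rose adjusted over the list alone. The interneuron list median was -0.45 (camera adjusted p = 8.73e-06; adjusted p = 0.489 with an estimated correlation), and its highest member *Kirrel2* stood at 13647 ± 2527 and 12687 ± 1984.

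The neural stem and radial glial list, with *Fabp7* at 125393 ± 12093 and 98491 ± 28365, had a median of -0.0573 and did not pass (camera adjusted p = 0.0902). It passed downward without control replicate 2, irradiated replicate 1 or irradiated replicate 2 (camera adjusted p = 0.00287, 0.0135 and 0.0158), and its median was 0.0386 without irradiated replicate 3 (camera adjusted p = 0.823). The oligodendrocyte lineage list, with *Pdgfra* at 14706 ± 3624 and 14333 ± 4077, did not pass (camera adjusted p = 0.797). Its median of -0.0163 and mean of -0.0159 went against an upward test. It passed upward without irradiated replicate 1 (median 0.20, camera adjusted p = 0.0473), and downward with the Y-linked covariate (median -0.34, camera adjusted p = 0.00407). Purkinje cell genes were shifted upward, 10 of 14 higher in the fit with none past the threshold (median 0.24, camera adjusted p = 0.0339; adjusted p = 0.525 with an estimated correlation). With the block *Calb1*, *Pvalb* and *Car8*, genes of calcium-binding proteins and a carbonic anhydrase-related protein, rose and *Lhx5* fell adjusted over the list alone. The Purkinje call ended without control replicate 1, control replicate 2 or irradiated replicate 3 (camera adjusted p = 0.42, 0.12 and 0.796), among genes with a mean of at least 50 (camera adjusted p = 0.133), and with the Y-linked covariate, where the median was -0.0534 (camera adjusted p = 0.426).

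**Figure D2:**
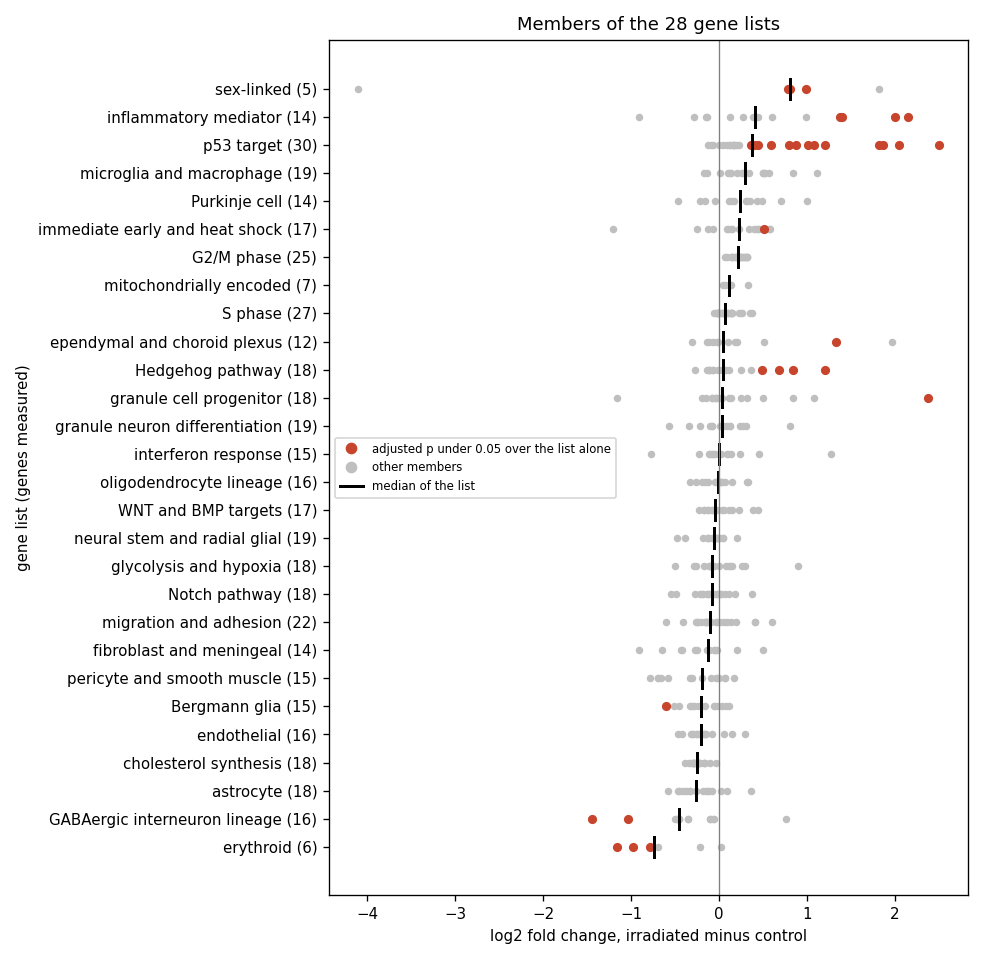
Log2 fold change (irradiated minus control, n = 3 against 3) of each measured member of the 28 gene lists, with the number of genes measured in brackets. Dots are genes, red where the adjusted p over the list alone is below 0.05, and black bars are list medians. The median is 0.38 for p53 targets, 0.22 for G2/M genes, -0.25 for cholesterol synthesis and -0.45 for the GABAergic interneuron lineage.

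Cell cycle genes of G2 and M phase were higher in all 25 members measured, by log2 fold changes of 0.0688 to 0.32, and none passed singly. *Top2a*, encoding topoisomerase II alpha, stood at 26160 ± 938 in controls and 30145 ± 2480 after irradiation, and *Mki67*, the Ki-67 gene, at 19124 ± 3384 and 23615 ± 2027. The list was shifted upward (median 0.22, camera adjusted p = 4.59e-14), and the adjusted p was 0.12 with an estimated correlation. S phase genes had 19 of 27 members higher in the fit, with *Rrm1* at 14473 ± 1238 and 15505 ± 1246 and none past the threshold. They were shifted upward (median 0.0653, camera adjusted p = 0.00299; adjusted p = 0.561 with an estimated correlation). The S phase call ended without control replicate 2 (camera adjusted p = 0.0698) and, with the direction turned in camera, without irradiated replicate 3 (camera adjusted p = 0.957) and with the Y-linked covariate (camera adjusted p = 0.688). All 18 cholesterol synthesis genes were lower in the fit, and none passed over all genes or over the list alone. *Hmgcs1*, encoding the HMG-CoA synthase of that pathway, stood at 26583 ± 3059 and 20658 ± 4861. The cholesterol list was shifted downward (median -0.25, camera adjusted p = 5.4e-10; adjusted p = 0.366 with an estimated correlation), and 7 of its genes fell adjusted over the list alone with the block.

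Immediate early and heat shock genes, which respond within minutes to stimulation and to tissue dissociation, were shifted upward (median 0.23, camera adjusted p = 0.000331; adjusted p = 0.26 with an estimated correlation). *Jun* rose adjusted over the list alone, from 4944 ± 470 to 7101 ± 995, and *Egr1*, the highest member, stood at 15976 ± 4543 and 21454 ± 2857. With the block *Jun*, *Junb*, *Egr1* and *Zfp36* rose adjusted over the list alone. With the Y-linked covariate the camera call ended (adjusted p = 0.334). Glycolysis and hypoxia genes did not pass (camera adjusted p = 0.915), with *Pkm* at 19438 ± 1892 and 21115 ± 1999, a median of -0.075, a mean of 0.00753 and a downward test. Mitochondrially encoded genes took 1.88 to 2.69% of the reads of a library. They were higher in the fit in 7 of 7 members, with *mt-Co1* at 248878 ± 8798 and 274902 ± 29948, and did not pass (median 0.12, camera adjusted p = 0.0732). This list passed without control replicate 2 or irradiated replicate 2 (camera adjusted p = 0.00534 and 0.00258), without the filter on low values (camera adjusted p = 0.0425) and under quantile normalization (camera adjusted p = 0.0323), and its median was -0.0399 with the Y-linked covariate (camera adjusted p = 0.847).

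Transcripts of immune cells were measurable in the sorted cells. The inflammatory mediator list was shifted upward (median 0.41, camera adjusted p = 0.000105; adjusted p = 0.366 with an estimated correlation), with no member past limma's threshold over all genes and 4 of 14 that rose adjusted over the list alone. *Tnf*, encoding tumour necrosis factor, rose from 30.2 ± 13.6 to 131 ± 42.3 and the interleukin gene *Il1a* from 10.6 ± 4.15 to 28.7 ± 8.76. The chemokine genes *Ccl12* and *Ccl4* rose from 9.75 ± 3.01 to 40.9 ± 4.97 and from 25.2 ± 11.9 to 63.2 ± 16.9. DESeq2 called *Tnf* and *Ccl12* over all genes (adjusted p = 0.000116 and 0.00726). *Nfkbia*, the highest member, stood at 1356 ± 111 and 1129 ± 236. The call ended with the Y-linked covariate (camera adjusted p = 0.426). Of 19 microglia and macrophage genes 17 were higher in the fit and none passed the threshold. That list was shifted upward (median 0.30, camera adjusted p = 0.000655; adjusted p = 0.575 with an estimated correlation). It did not pass without control replicate 1, where the median was -0.0294 (camera adjusted p = 0.836), without irradiated replicate 3 (camera adjusted p = 0.213) or with the Y-linked covariate, where it was -0.16 (camera adjusted p = 0.114). Interferon response genes did not pass (camera adjusted p = 0.78), with *Ifit2* at 576 ± 66.9 and 686 ± 149, a median of -0.0019, a mean of 0.0594 and an upward test.

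Cells of blood vessels, blood, meninges and ventricles were covered by further lists. In the endothelial list 13 of 16 genes were lower in the fit, with *Slc2a1*, the glucose transporter gene, at 1268 ± 155 and 1065 ± 76.3. The list was shifted downward with no member past the threshold (median -0.20, camera adjusted p = 0.002; adjusted p = 0.525 with an estimated correlation). Without control replicate 1 or irradiated replicate 1, or with the Y-linked covariate, the endothelial call ended (camera adjusted p = 0.127, 0.352 and 0.222). Pericyte and smooth muscle genes had 11 of 15 members lower in the fit, with *Notch3* at 6663 ± 1566 and 5926 ± 1822 and none past the threshold. Their list was shifted downward (median -0.20, camera adjusted p = 0.00559; adjusted p = 0.489 with an estimated correlation), and its call ended without the same 2 libraries (camera adjusted p = 0.0897 and 0.26). Of 6 erythroid genes none passed limma over all genes and 3 globin genes fell adjusted over the list alone. *Hbb-bs* fell from 364 ± 81.0 to 208 ± 14.3, *Hba-a1* from 200.9 ± 58.9 to 99.5 ± 17.9, and *Hbb-bt* from 64.5 ± 26.8 to 28.2 ± 12.4. DESeq2 called *Hbb-bs* and *Hba-a1* over all genes (adjusted p = 0.0238 and 0.0497). These globin genes have near-identical copies, so counts of a single copy are uncertain. The erythroid list was shifted downward (median -0.74, camera adjusted p = 3.06e-05; adjusted p = 0.366 with an estimated correlation), and its highest member *Bpgm* stood at 2484 ± 250 and 2519 ± 160. Fibroblast and meningeal genes, whose highest member was again *Pdgfra*, did not pass (median -0.12, camera adjusted p = 0.0821). They passed downward without control replicate 3, irradiated replicate 2 or irradiated replicate 3 (camera adjusted p = 0.0494, 0.00962 and 0.0109). The median was 0.0394 without irradiated replicate 1 (camera adjusted p = 0.511). Ependymal and choroid plexus genes did not pass (median 0.0501, camera adjusted p = 0.125), with *Enpp2* at 4370 ± 752 and 3940 ± 219. *Clic6*, a choroid plexus gene, rose adjusted over the list alone from 89.3 ± 15.6 to 227 ± 51.5, and with the block so did *Foxj1*. DESeq2 called *Clic6* over all genes (adjusted p = 0.00014). The list passed upward with edgeR and DESeq2 (camera adjusted p = 0.0489 and 0.04) and without irradiated replicate 1 or 2 (camera adjusted p = 0.0324 and 0.033).

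The libraries also differed in transcripts of the sex chromosomes. *Xist*, expressed from the inactive X chromosome of females, stood at 31250, 85481 and 32870 in control replicates 1, 2 and 3 and at 30165, 21073 and 26.2 in irradiated replicates 1, 2 and 3 (log2 fold change -4.10, SE 2.17, limma adjusted p = 1). This fold change rests on irradiated replicate 3: it was -0.818 without that library and down to -5.88 without another, and edgeR and DESeq2 gave -1.56 and -1.55. The Y-linked gene *Ddx3y* stood at 144, 806 and 2058 in the controls and at 1404, 1893 and 3916 in the irradiated libraries. The other Y-linked genes spread less between libraries. *Eif2s3y* stood at 588, 663 and 1383 against 1114, 1419 and 2644, and *Uty* at 279, 314 and 594 against 568, 635 and 744. *Kdm5d* stood at 526, 520 and 1059 against 853, 1138 and 1608. The other libraries held both kinds of transcript, and irradiated replicate 3 almost none of *Xist*. The sex-linked list, of which *Kdm5d*, *Uty* and *Eif2s3y* rose adjusted over the list alone, had a median of 0.81 and a mean of 0.058 (camera adjusted p = 0.00201; adjusted p = 0.366 with an estimated correlation). *Eif2s3y* passed over all genes with the block (limma adjusted p = 0.0348), and with the block 4 of the 5 genes rose and *Xist* fell adjusted over the list alone. The list did not pass without control replicate 1 (camera adjusted p = 0.0689) or with its own Y-linked members as covariate (camera adjusted p = 0.944).

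In principal components of 13900 genes, the first component took 40.8% of the variance and did not part the groups. Irradiated replicate 3 lay at 34.27 on it, apart from irradiated replicates 1 and 2 at -17.2 and -0.28, while the controls lay at -19.89, -9.52 and 12.63. The score thus rose with the replicate number in both groups, and within each number it was higher in the irradiated library. Of the 28 lists, camera with its preset correlation called 16, 9 upward and 7 downward, and camera with an estimated correlation called 0, as did fry. At an unadjusted p below 0.05, both tests moved 3 lists upward. These were p53 targets (p = 0.00403 with an estimated correlation and 0.00184 by fry), G2 and M phase genes (p = 0.00854 and 0.00584) and immediate early and heat shock genes (p = 0.0278 and 0.0415).

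**Figure D3:**
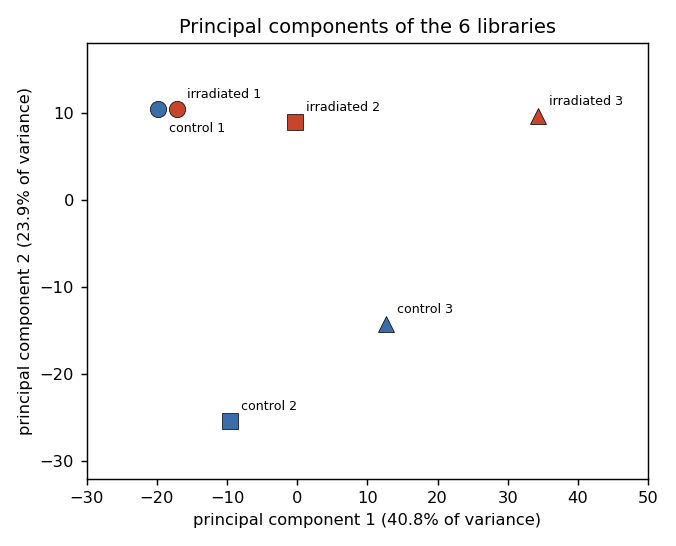
Scores of the 6 libraries on the first 2 principal components of log2(scaled count + 1) over 13900 genes (component 1, 40.8% of the variance; component 2, 23.9%). Blue points are control and red points irradiated libraries, with symbols for the replicate number. Irradiated replicate 3 lies at 34.27 on component 1 and the other libraries lie between -19.89 and 12.63.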

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

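The covariate of Y-linked genes and edgeR with the replicate block were chosen after the data were seen. With pseudocounts of 0.5 and 5, without the filter, and under TMM or quantile scaling the same 9 genes were called, and edgeR called 8 of them. The 9 genes kept their direction in the settings that tested them, and the mean of at least 50, which left 7 of them to test, called 6, with 1 lower. DESeq2 called 104 genes, 76 higher and 28 lower, 69 of them at least 2-fold, among them the 9. In simulated data with 200 genes changed in each set, DESeq2 called 34.2 unchanged genes against 9.8 for limma. Such counts depend on how many genes are changed, so they do not give the number of false calls in the real data. The replicate block called 25 genes, 21 higher and 4 lower, 22 at least 2-fold, among them the 9. Adjusted over the list alone it added *Syt1*, *Agt* and *L1cam* among genes that fell and *Laptm5*, *Fbln1*, *Robo2* and *Hk2* among those that rose, and *Hbb-bt* missed the threshold. Among the lists and the genes named in the text, it changed no call beyond these and those given with each gene or list, and 8 more genes that it added over all genes are not named. Under the block WNT and BMP targets turned downward in camera (median -0.0425). edgeR with the block called 8 genes, 4 of them among the 9 and 1 lower. The granule cell progenitor list passed there (median 0.0215, adjusted p = 0.02, range over its alternatives 0.00171 to 0.823), and WNT and BMP targets turned (-0.0528). Camera with an estimated correlation and fry called 0 lists. The cause of these differences was not tested.

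With the Y-linked covariate 28 genes passed, 18 higher and 10 lower, 26 at least 2-fold, and 9 lists. List medians turned for granule cell progenitors (-0.0602), granule neuron differentiation (-0.218), microglia (-0.156), Purkinje cells (-0.0534), mitochondrial genes (-0.0399), Bergmann glia (0.0862), glycolysis (0.0977), migration (0.0427) and WNT and BMP targets (0.107). Without a change of sign, medians moved by over 1.5 times for G2/M (0.129), cholesterol synthesis (-0.122), interneurons (-0.953), astrocytes (-0.165), pericytes (-0.353), inflammatory mediators (0.201), immediate early genes (0.07), sex-linked genes (0.0564), Notch (-0.0154), ependyma (0.165), fibroblasts (-0.241) and interferon response (-0.0116), as did fold changes of, among others, *Atoh1* (0.421), *Nes* (0.484) and *Gli1* (0.431). The camera direction turned for neural stem genes (median -0.00625), oligodendrocytes (-0.335) and S phase (0.00171). Fold changes turned for *Slc1a3* (0.20), *Notch3* (0.272), *Bpgm* (-0.0146), *Ifit2* (-0.069), *Nrcam* (0.091) and *Id2* (0.0718), none past the threshold. *Zic1* turned under quantile scaling (0.052), and the camera direction of glycolysis under edgeR (median -0.0869) and DESeq2 (-0.0774). *Ddx3y*, *Eif2s3y* and *Uty* rose with the replicate number in both groups, as did the score on the first principal component. These moves can therefore not be read as an effect of sex alone, and the cause was not tested.

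Leaving out 1 library at a time, which also leaves fewer samples, gave 1 to 29 genes, 1 to 26 higher and 0 to 3 lower, 1 to 29 at least 2-fold, and 10 to 21 lists. Medians ranged from -0.0181 to 0.17 for granule cell progenitors, 0.0162 to 0.139 for S phase, -0.0913 to 0.0178 for WNT and BMP targets, -0.295 to 0.0394 for fibroblasts, -0.0992 to 0.0553 for glycolysis, -0.0659 to 0.125 for granule neuron differentiation, -0.105 to 0.108 for interferon response, -0.0294 to 0.514 for microglia, -0.116 to 0.0386 for neural stem genes, -0.165 to 0.195 for oligodendrocytes, -0.0207 to 0.223 for mitochondrial genes, -0.0661 to 0.176 for ependyma, -0.156 to 0.006 for Notch and -0.00685 to 0.13 for Hedgehog. The median of migration and adhesion, which kept its sign, ranged from -0.172 to -0.014. Among called lists that kept their sign, medians ranged from -0.707 to -0.231 for the interneuron lineage, 0.244 to 0.669 for inflammatory mediators, -0.348 to -0.153 for astrocytes, -0.386 to -0.0236 for Bergmann glia, -0.271 to -0.0564 for endothelium, 0.00525 to 0.368 for Purkinje cells, -0.897 to -0.489 for erythroid genes and 0.138 to 0.294 for immediate early and heat shock genes. Fold changes ranged from 0.0204 to 0.448 for *Nes*, 0.142 to 0.354 for *Gli1*, 0.789 to 1.42 for *Atoh1*, -0.0622 to 0.0764 for *Bpgm*, -0.162 to 0.0892 for *Id2*, -0.221 to 0.0462 for *Kirrel2*, -0.365 to 0.0887 for *Notch3*, -0.19 to 0.0304 for *Nrcam*, -0.269 to 0.174 for *Pdgfra* and -0.315 to 0.0539 for *Slc1a3*. Depth limits *Foxa2* and *Cdh1*, with 5 and 3 reads over the libraries of 1 group.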

Other observations

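The tests on sex, on library depth, on the balance of granule and glial genes and on granule progenitors were chosen after the results were seen, except the share of X and Y genes and the splits of the samples. The 8 genes outside the lists that follow were picked after their values were seen, had no test as a set, and did not pass limma over all genes without the block. *Myod1*, the muscle determination gene, stood at 19.7 ± 16.6 in controls and 252 ± 135 after irradiation (log2 fold change 3.76, limma adjusted p = 0.1; 0.0348 with the replicate block), and *Cdh15*, encoding M-cadherin, at 25.5 ± 17.6 and 215 ± 103 (3.12, limma adjusted p = 0.169; 0.0901 with the block). The homeobox gene *Tlx3* stood at 47.1 ± 31.4 and 282 ± 160 (2.56, limma adjusted p = 0.228; 0.0442 with the block), the ephrin receptor gene *Epha8* at 186 ± 35.5 and 1470 ± 849 (2.78, limma adjusted p = 0.106; 0.0711 with the block), and the neurotrophin receptor gene *Ngfr* at 318 ± 141 and 1285 ± 647 (1.96, limma adjusted p = 0.236; 0.0442 with the block). The groups did not overlap for these 5 genes, and DESeq2 called them all at adjusted p from 3.11e-09 to 0.0497. Under edgeR with the block the adjusted p of *Tlx3* and *Ngfr* was 0.0514.

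Among genes with lower levels, *Slc17a6*, encoding a vesicular glutamate transporter, stood at 421 ± 167 in controls and 104 ± 51.7 after irradiation (log2 fold change -2.04, limma adjusted p = 0.183; 0.0246 with the block). *Eomes*, known as a marker of unipolar brush cells in the cerebellum, stood at 829 ± 118 and 390 ± 78.0 (-1.10, limma adjusted p = 0.151; 0.1 with the block). The cadherin gene *Cdh3* stood at 101 ± 23.2 and 36.4 ± 2.03 (-1.42, limma adjusted p = 0.169; 0.1 with the block). DESeq2 called these 3 genes at adjusted p from 3.23e-05 to 0.00137, and the groups did not overlap for any of them.

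The first pattern weighed is the set of 9 genes, given that sex-linked transcripts also differed between the libraries. With the Y-linked level as a covariate, the median over the 9 genes of the ratio of log2 fold change with and without it was 1.06, which argues against the sex of the sorted animals as the whole cause. The calls of *Cdh1* and *Slc39a12* ended at nearly the same fold change, with log2 values of -4.49 (SE 0.495) and 1.08 (SE 0.14) before and -4.27 (SE 0.699) and 1.01 (SE 0.183) after, as the standard errors grew. That fit had 1 residual degree of freedom fewer. Every Y-linked gene of the covariate was also higher in the irradiated library of each pair. The covariate is thus partly confounded with irradiation, which limits what this test says on sex. The 6 samples make 10 splits into 3 and 3, too few for a share under 0.05, and 1 of them, the real one, gave 9 genes, all 9 at least 2-fold, against 0 in the highest of the others, including the other 3 that part all 3 pairs. Radiation itself stays open as a candidate explanation of the 9 genes.

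The same 10 splits are too few for the lists as well. As many lists as in the real split, 16, were moved in 3 of the 10, with 17 in the highest other, and the other 3 splits that part all 3 pairs moved 12, 17 and 10. For granule cell progenitors 6 of the 10 splits gave a camera p as small as the real one, with a -log10 p of 0.955 in the real split and 5.58 in the highest other, which set control replicates 1 and 2 and irradiated replicate 1 against the rest.

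The second pattern is irradiated replicate 3, which lay far from irradiated replicates 1 and 2. Its total reads were 1.002 times their mean, which argues against library depth. Genes on X and Y gave 7.45% of its squared log2 distance from replicates 1 and 2, with 3.65% of the genes, so these genes were not the main source of the distance. That share leaves out any effect of sex on genes of other chromosomes. Sex therefore stays open, and this library alone had almost no *Xist* (26.2). Another balance of granule neuron and glial cells in that sort is a candidate explanation, since the median log2 difference from replicates 1 and 2 was 0.44 over 19 granule neuron genes and -0.40 over 52 genes of neural stem cells, Bergmann glia and astrocytes, a gap of 0.841. The same balance was -0.374, 0.0315 and 0.0608 in the controls and -0.379, 0.0626 and 0.689 in the irradiated libraries, in the order of their numbers. It thus rose with the replicate number in both groups. A difference between animals stays open and was not tested.

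The third pattern is the higher fitted level of *Atoh1* and of the Hedgehog pathway genes *Ptch1*, *Sfrp1* and *Ccnd1* in irradiated cells, none of which passed limma over all genes, while DESeq2 called *Sfrp1* and *Ccnd1*. More granule cell progenitors of the same kind would raise other genes of that lineage alike only if the same cells express them, which was not tested. A first form of the test found a difference of 0.18 (SE 0.387, or 0.169 paired by number, with 2 of 3 pairs higher) in the mean log2 level of *Barhl1*, *Barhl2*, *Cntn2*, *Nhlh1*, *Neurod1* and *Insm1* (two-sided exact permutation p = 0.7, where the design allows no p below 0.1). Relative to those 6 genes, *Atoh1* was higher by 0.899 (SE 0.18, or 0.212 paired by number). The groups did not overlap, which chance gives for 10% of genes. This argues only against more progenitors in which *Atoh1* and the 6 genes keep their proportions. If some of the 6 genes belong to later cells of the lineage, more progenitors could give the same difference, and the test cannot decide between these. The weight is also limited, since this form was set up after the first result, with the levels of the 6 genes known. More progenitors of a kind with more *Atoh1* relative to the 6 genes stay open. With the Y-linked covariate the rise of *Atoh1* itself fell from 1.08 to 0.421, while the mean of the 6 genes was lower by 0.447 (SE 0.276) and *Atoh1* relative to them higher by 0.868 (SE 0.281). The mean of the 3 Hedgehog genes was higher by 0.659 (SE 0.274). The groups overlapped, yet with libraries paired by number, a form added later, it was higher in 3 of 3 pairs, by 0.44 to 0.815 (SE 0.113), and with the covariate by 1.16 (SE 0.0462). The fits with the covariate here left only 3 residual degrees of freedom, and the covariate is partly confounded with irradiation. The 3 genes had been picked for being higher, which by itself raises these values, so more progenitors stay open for them, and a shift towards an earlier progenitor stage was not tested. A response to irradiation stays open for *Atoh1*, and no test here decides it.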
